A study of Zea mays with 6 samples.

How the data were processed

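The series compared developing ears of maize, Zea mays, from plants inoculated with Sporisorium reilianum, the fungus that causes maize head smut, with ears of mock-treated plants. All 6 samples were taken 4 weeks after inoculation, 3 from infected and 3 from mock-treated plants. Per the labels' protocols, each sample pooled ears of 20 plants, RNA came from 3 independent experiments, and infected ears with clear vegetative structures had been left out so that those with elongated spikelets remained. The labels disagree on ear length (under or over 2 cm), and the source name of the mock samples repeats that of the infected ones, so groups were taken from the titles and the infection status. Biotin-labelled RNA was hybridised to an Affymetrix maize array, which reads 1 sample per array. A probe set is a group of short probes for 1 transcript.

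The values analysed were the deposited signal intensities on a linear scale, 1 per probe set and array. GCOS 1.4 is named in the submitters' processing notes. The background correction, the scaling target and the way probes were summarised are not given in the sources used here. The deposited table held 17734 probe sets, of which 113 were control probe sets and were left out of all comparisons, so 17621 were tested. The median deposited intensity was 138.4, 218.5 and 244.0 in infected replicates 1, 2 and 3 and 142.0, 224.4 and 264.5 in mock replicates 1, 2 and 3. No pair of arrays shared an identical value.

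Each array was multiplied by 1 factor so that its median equalled the common median of 199.0, values under a floor of 32 were raised to it, and log2 was taken. Between 26.2% and 28.2% of probe sets lay at the floor on each array. A change of the mean log2 value that passed a test is a lower bound in size, written as "at least", where 1 or more arrays of the lower group were raised to the floor. For genes near the floor that did not pass, changes are those of the floored values. A group with all its arrays raised to the floor shows no spread. The error and p-value then leave out the true spread of that group, and the error can be too small. Infected and mock ears were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05). Adjusted p-values are from this test, and errors of log2 changes are its moderated standard errors. The number of arrays limits the precision.

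This design, the named-gene rule, 19 gene lists (4 of them tissue markers) and most alternatives were fixed before the data were examined. Of the 17621 probe sets, 4192 lay at the floor on all 6 arrays and had no variance. They lowered the prior degrees of freedom of the variance model from 2.61, the value without them, to 0.396. For this reason each comparison gives the planned fit over all 17621 probe sets and, beside it, a filter, also fixed in advance, that leaves out the dimmest 25% (13215 probe sets remain, prior degrees of freedom 3.17). The prominence given to the second fit was decided after both had been seen. The plan did not say on which scale dimness is averaged. The mean of the linear values was tried first and gave 265 changed probe sets. The mean of the log2 values, which gave 355, was taken after that count had been seen, because it removes every probe set without variance. All 265 were among the 355.

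Simulated data had the real means and spreads, and 200 changed probe sets drawn only from those with a mean log2 signal above that of 64. The noise was drawn independently for each probe set and array, so deviations shared by replicates or by genes were left out. Recovery and false calls on the real arrays can therefore differ. The fit over all 17621 probe sets recovered 45.0% of 2-fold changes with 13 false calls and 84.0% of 4-fold changes with 15. Without the dimmest 25%, on 13215 probe sets, 72.0% of 2-fold changes were recovered with 13 false calls and 94.5% of 4-fold changes with 10. Of 1.5-fold changes, 3.5% and 0% were recovered.

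Replicates with the same number varied together. The correlation of their deviations from the group means was 0.32, 0.30 and 0.27 for numbers 1, 2 and 3 over 12211 probe sets above the floor on all arrays, against at most 0.06 for arrays of different numbers. The numbers may therefore pair the samples. The main fits and list tests kept the planned design without a block, so they leave this pairing out. Values with the replicate number as a block are given beside them where they change the count of calls of a list or end the call of a named gene. Where several probe sets name 1 gene, values are those of the probe set named by the rule below, and other probe sets that do not pass are given beside it.

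Gene names came from the platform annotation of 2007, updated through gene IDs to the gene table of assembly Zm-B73-REFERENCE-NAM-5.0. The annotation lists 1453 of the tested probe sets, 1452 with 1 gene symbol and 1 with several, and 16168 are unnamed here. The gene table held 1377 of them. A total of 1259 probe sets, for 970 genes, had a name other than a locus or clone number, so lists cover few of the genes on the array. Lists were matched on symbols and synonyms. From the names alone, before any list was tested, 24 matches whose symbol belonged to another gene, or that are not known as members of the class, were removed, which departs from the plan, and the lists as first matched are an added alternative. Lists were tested with camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the 19 lists. Counts within a list are given over all probe sets tested and adjusted over the list alone.

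Named genes were chosen by rule. The rule took up to 10 named genes with the largest rise and 10 with the largest fall among those past the threshold whose groups did not overlap. It added up to 3 genes with the smallest p per list, each changed gene of the floral organ and meristem lists, and 19 fixed developmental genes, of which 11 had a named probe set. Applying it to the fit without the dimmest 25% was added after the data were seen. The alternatives run were quantile normalization, a 2% trimmed mean for scaling, no scaling, floors of 1 and 64, other filters on dim probe sets, a variance trend, array weights, the replicate block, other thresholds, leaving out probe sets marked as reading several transcripts, averaging by gene, other list tests and leaving out each array in turn. Centring on the median alone is the scaling already used.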

Results

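The data are the scaled signals of 17621 probe sets in ears of 3 infected and 3 mock-treated samples of maize, 4 weeks after inoculation with the head smut fungus Sporisorium reilianum. The sample titles call the infected ears leafy, while the protocol says that ears with clear vegetative structures were left out. Over 12211 probe sets above the floor on all arrays, log2 signals correlated at 0.974 to 0.985 within groups and 0.951 to 0.973 between groups. The scaled signal of the 18S rRNA control differed widely between arrays. It was 19.9, 91.6 and 1233.1 in infected replicates 1, 2 and 3 and 22.3, 343.2 and 24.1 in the mock replicates. The mean ratio of 3' to 5' signal of 5 control genes, a sign of RNA integrity, was 2.14, 2.42 and 2.80 in infected replicates 1, 2 and 3 and 2.47, 3.28 and 2.34 in the mock replicates. On the log2 scale it was 1.29 ± 0.19 (SD, n = 3) in infected and 1.42 ± 0.26 (SD, n = 3) in mock ears (exact two-sided permutation p = 0.60, where 0.1 is the smallest p that 3 against 3 arrays allow).

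The terpene synthase gene tps6 had a signal of 1730 ± 193 (SD, n = 3) in infected and 33.2 ± 1.54 (SD, n = 3) in mock ears, close to the floor of 32. Over all 17621 probe sets, 52 changed at the threshold, 33 higher and 19 lower in infected ears, and 24 of them by at least 2-fold (16 higher, 8 lower). Without the dimmest 25% of probe sets, 355 changed, 214 higher and 141 lower, and 151 by at least 2-fold (97 higher, 54 lower). The fits shared 40 calls. With dimness averaged on the linear scale, the second count was 265. With the replicate number as a block, the counts were 7 (5 higher, 2 lower) and 591 (284 higher, 307 lower), so the excess of rises without the dimmest 25% was not seen with the block, and none of the 7 was among the 52. Leaving out single arrays gave between 0 (without mock replicate 3) and 30 calls (without mock replicate 1) over all probe sets, and between 46 (without infected replicate 1) and 167 (without mock replicate 1) without the dimmest 25%. Without mock replicate 2, whose 3' to 5' ratio was the highest, the counts were 7 and 94.

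Of the 52 probe sets, 7 had a named gene. The genes tps6, bx1, bx6 and an2 rose, as did the MADS-box gene m21 and the tonoplast aquaporin gene tip1, and GA20 fell. The change of tps6 was at least 5.69 ± 0.09 on the log2 scale (SE, adjusted p = 0.00215), and bx1, whose enzyme starts benzoxazinoid synthesis, rose by 3.03 ± 0.19 (adjusted p = 0.034). The gene bx6 of the same pathway rose by 0.70 ± 0.05 (adjusted p = 0.0415), and its other probe set had a change of 0.80 (adjusted p = 0.182). The signal of an2, an ent-copalyl diphosphate synthase gene, was 93.3 ± 15.2 (SD, n = 3) in infected ears and under the floor on all mock arrays, at least 2.89-fold higher (adjusted p = 0.0499). The change of m21 was 1.54 ± 0.07 (adjusted p = 0.024) in 1 probe set, while another near the floor did not pass (adjusted p = 0.834). The change of tip1 was 0.39 ± 0.02 (adjusted p = 0.024) and that of GA20 -1.69 ± 0.12 (adjusted p = 0.0417). With the replicate block none of these 7 passed over all probe sets (tps6 adjusted p = 0.0747), while all except tip1 passed without the dimmest 25%, with and without the block. A near-identical copy of tps6 can contribute to its signal. Of the probe sets with no gene name here, the largest rise was at least 11.6-fold (377.5 ± 97.5 in infected ears, SD, n = 3, adjusted p = 0.0285). Its signal was under the floor on all mock arrays. The largest fall was to 95.3 ± 12.1 from 328 ± 35 in mock ears (SD, n = 3, adjusted p = 0.0451).

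Floral organ identity genes formed the list with the lowest median. Its 26 probe sets stand for 24 genes, mostly MADS-box transcription factors that specify floral organs and meristems. No member passed over all probe sets, and 14 passed when adjusted over the list alone. In the fit without the dimmest 25%, 7 of 24 probe sets fell, 1 rose and 16 did not pass (12 lower and 3 higher when adjusted over the list alone). The ovule-related gene zag2 changed by -1.98 ± 0.18 on the log2 scale (SE, adjusted p = 0.0043), from 524.0 ± 99.9 (SD, n = 3) in mock to 132.8 ± 21.9 (SD, n = 3) in infected ears. The B-class gene zmm29 changed by -1.84 ± 0.18 (adjusted p = 0.00665), the AGL6-type gene zag3 by -1.34 ± 0.16 (adjusted p = 0.0125) and the C-class gene zag1 by -1.16 ± 0.18 (adjusted p = 0.026). Smaller falls were seen for zmm6 (-0.86), zmm14 (-0.81) and M7 (-0.77), with adjusted p between 0.0183 and 0.0418. The probe set of M7 that fell is marked as reading several transcripts. The other probe set of M7 did not pass (-0.47, adjusted p = 0.104), and that of zmm14 was at the floor. With the replicate block 6 fell and 1 rose, as the call of zmm14 was lost (adjusted p = 0.0694). The member that rose was zmm19, the gene of the tunicate locus, by 0.82 ± 0.11 (adjusted p = 0.0205). Outside the list, m1 changed by -2.41 ± 0.22 (adjusted p = 0.0043) and m25, raised to the floor on 1 infected array, by at least -1.40 ± 0.20 in size (adjusted p = 0.0212). Members that did not pass had changes from -0.89 (M8, adjusted p = 0.0701) to 0.67 (m5, adjusted p = 0.174), with si1 (0.10 ± 0.15) and zmm24 (-0.03 ± 0.16) between them. As a list the genes were lower by camera (adjusted p = 0.000162), with adjusted p = 0.379 with an estimated correlation. The pairs zag2 and m1, and zmm29 and its close copy, are so alike that their probe sets may not tell them apart.

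**Figure D1:**
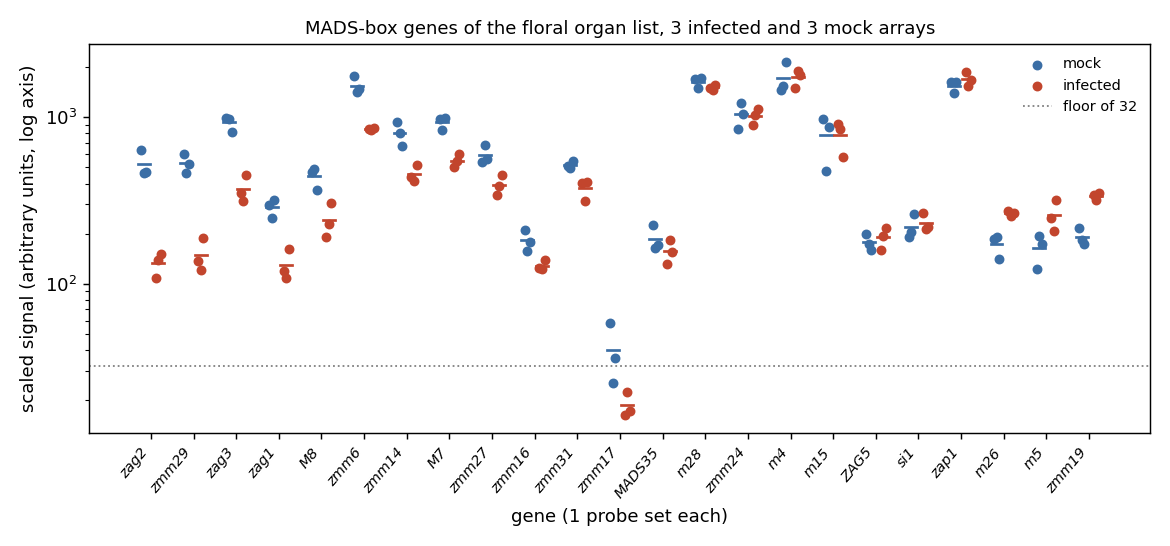
Scaled signal (log axis, arbitrary units) of 1 probe set for each gene of the floral organ list outside the dimmest 25%, ordered by log2 change. Points are the 3 arrays of each group, bars their mean and the dotted line the floor of 32. The points of zag2 lie at 524.0 on average in mock and at 132.8 in infected ears, and those of zmm19 at 191.3 and 336.5.

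The list of defence genes was higher in infected ears by camera (adjusted p = 0.000665), with adjusted p = 0.379 with an estimated correlation. Of its 26 probe sets, 3 rose over all probe sets (tps6, bx1 and bx6) and none fell, with 7 past the threshold when adjusted over the list alone. Outside the dimmest 25%, 5 of 19 probe sets rose, 1 fell and 13 did not pass (7 higher and 1 lower when adjusted over the list alone). With the replicate block 8 rose and 1 fell, the added calls being bx6 (its other probe set), 1 of 2 probe sets of sip1, and chn1. PR-1, a pathogenesis-related protein gene, was under the floor on all mock arrays and reached 120.4 ± 41.6 (SD, n = 3) in infected ears, at least 3.62-fold higher (adjusted p = 0.0144). Its probe set is marked as reading several transcripts. The beta-glucosidase gene glu1 rose by 1.66 ± 0.31 (adjusted p = 0.0438). The gene rip2, for a ribosome-inactivating protein, changed by -1.04 ± 0.17 (adjusted p = 0.0289).

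Of the members of the list of reactive oxygen genes that rose, most were glutathione transferases, which conjugate glutathione to electrophiles. The list itself holds many of this family, so their number among the rises may reflect its make-up. A separate list of glutathione transferases, tested below, has 35 probe sets, 30 of them outside the dimmest 25%. Of the 58 probe sets of the reactive oxygen list, none passed over all probe sets and 13 did when adjusted over the list alone. Outside the dimmest 25%, 10 of 47 rose, none fell and 37 did not pass (16 higher and 2 lower when adjusted over the list alone). With the replicate block 11 rose and 1 fell, as gst14 was added and gst19 had a change of -1.88 (adjusted p = 0.02 with the block, 0.0565 without). Among those that rose were gst2 (2.67 ± 0.39, adjusted p = 0.0238), GST25 (at least 2.15 ± 0.19, adjusted p = 0.0043), aox3 (at least 1.34 ± 0.18, adjusted p = 0.019) and gst5 (1.23 ± 0.12, adjusted p = 0.00569). Of 4 probe sets of gst31, 2 under the floor on all mock arrays rose. The higher, marked as reading several transcripts, rose by at least 3.34-fold (adjusted p = 0.013). The other 2, with mock signals near the floor, did not pass (1.81-fold and 1.95-fold from floored values, adjusted p = 0.0583 and 0.105). Among the 9 genes that rose, aox3, an alternative oxidase, and per-1, a peroxidase, were the only ones outside the glutathione transferases. By camera the list was higher (adjusted p = 0.000339), with adjusted p = 0.379 with an estimated correlation.

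**Figure D2:**
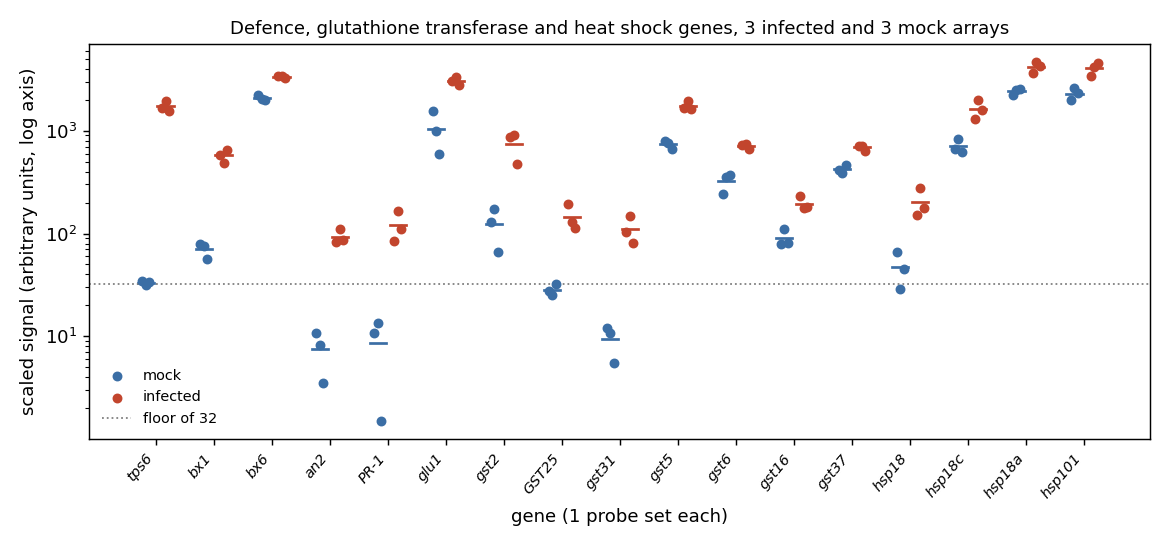
Scaled signal (log axis, arbitrary units) of defence, glutathione transferase and heat shock genes that rose, and of an2 from the gibberellin list, 1 probe set each. The defence gene rip2, which fell, is not shown. Points are the 3 arrays of each group, bars their mean and the dotted line the floor of 32. All infected points lie above all mock points, as they were chosen to do, and tps6 has means of 1730 and 33.2.

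The list of heat shock and chaperone genes was higher by camera (adjusted p = 3.97e-08), with adjusted p = 0.379 with an estimated correlation. None of its 15 probe sets passed over all probe sets, and 7 did when adjusted over the list alone. Without the dimmest 25%, 4 rose (hsp18, hsp18c, hsp18a and hsp101), none fell and 11 did not pass. The small heat shock protein gene hsp18 rose by at least 2.09 ± 0.31 (adjusted p = 0.0249), a call lost with the replicate block (adjusted p = 0.0556), and hsp101 by 0.81 ± 0.15 (adjusted p = 0.0399). A further probe set of hsp18c, near the floor, did not pass (adjusted p = 0.409), and with the block CPN60I passed (adjusted p = 0.0495). Ribosomal protein genes had a median log2 change of 0.17, from -0.15 (RPS10) to 0.52 (rpl29), and none of 19 probe sets passed over all probe sets, none of 18 without the dimmest 25%, and none over the list alone. Over the whole array 52 of 17621 probe sets passed, and 355 of 13215 without the dimmest 25%. By limma's unadjusted p, 2421 of all 17621 probe sets lay under 0.05. Camera gave adjusted p = 3.56e-05 for this list, and adjusted p = 0.379 with an estimated correlation.

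Of 33 probe sets of genes of meristems and branching none passed over all probe sets and 3 did when adjusted over the list alone. Without the dimmest 25%, the SBP-box gene ub2 changed by -0.67 ± 0.12 (adjusted p = 0.0418) and yab10 by -0.59 ± 0.12 (adjusted p = 0.0479), a call lost with the replicate block (adjusted p = 0.0567). The SBP-box gene sbp4 was under the floor on all mock arrays and at least 1.66-fold higher in infected ears (adjusted p = 0.0186). The remaining 21 probe sets did not pass. The meristem gene kn1 had a log2 change of 0.21 ± 0.13 (adjusted p = 0.456) and the branching gene tb1 of 0.24 ± 0.10 (adjusted p = 0.286). For fea2, ids1, ts2, ba1 and both probe sets of zfl1, changes lay between -0.18 and 0.44, and bd1 and te1 were at the floor on all 6 arrays. By camera the list did not pass (adjusted p = 0.637).

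Markers of other tissues were compared in the same way. Of the 25 probe sets of the green leaf list, none passed over all probe sets, 2 did when adjusted over the list alone, and without the dimmest 25% lhcb5, a light-harvesting protein gene, rose by 0.92 ± 0.13 (adjusted p = 0.0203) and OEE3 of photosystem II by 0.95 ± 0.15 (adjusted p = 0.0272). With the replicate block 2 of 4 probe sets of lhcb6 also rose (0.92 and 1.09, adjusted p = 0.0378 and 0.0474). The C4 photosynthesis gene pep1 was at the floor on all arrays, me3 had a change of -0.06 ± 0.10 and rbcs1 of 0.55 ± 0.27 (adjusted p = 0.354). The leaf list gave adjusted p = 0.0801 by camera over all probe sets, 0.025 without the dimmest 25%, and 0.0663 there with the replicate block. With an estimated correlation its adjusted p was 0.80. Kernel markers (42 probe sets, adjusted p = 0.738), pollen and anther markers (6 probe sets, adjusted p = 0.782) and root or vascular markers (15 probe sets, adjusted p = 0.637) did not pass as lists, and 35 kernel probe sets were in the dimmest 25%. The embryo storage protein gene glb1, on the kernel list, changed by -0.97 ± 0.18 (adjusted p = 0.045).

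Hormone, cell wall and metabolic lists did not pass as lists. Camera's adjusted p was 0.598 for auxin, 0.782 for cytokinin, 0.589 for gibberellin, 0.738 for jasmonate, lipoxygenase and ethylene, 0.589 for phenylpropanoid and flavonoid, 0.598 for cell wall, 0.138 for cell cycle and histone, 0.598 for sugar and starch and 0.589 for dehydration and seed maturation genes. Single members changed without the dimmest 25%. The cytokinin oxidase gene cko2 rose by 1.09 ± 0.19 (adjusted p = 0.0386), and the cell wall genes expB4 (1.92 ± 0.30, adjusted p = 0.0279) and expA4 (1.21 ± 0.14, adjusted p = 0.0114), both expansins, rose together with EXPA5 and expB8, while 2 further probe sets each of expA4 (0.31 and 0.37) and expB8 (0.25 and 0.27) did not pass. With the replicate block 3 cell wall probe sets fell, of bk2, CesA-4 (1 of 2 probe sets) and expB6 (adjusted p = 0.025, 0.0303 and 0.045). The block also added a fall of esp5 and rises of BM1 and 1 of 2 probe sets of cko3. The gene ACO, with the symbol of the ethylene-forming oxidase, rose by at least 1.37 ± 0.24 (adjusted p = 0.0381). The flavonoid gene a2 changed by -0.80 ± 0.14 (adjusted p = 0.0399). Outside the lists, umi11, a cyclotide-like gene, rose by at least 2.40 ± 0.27 (adjusted p = 0.0104), while pht7, a gene with a phosphate transporter symbol, changed by -1.29 ± 0.25 (adjusted p = 0.0476) and endo1 fell by at least 1.12 ± 0.20 (adjusted p = 0.0386). Of 61 named genes called without the dimmest 25%, 40 were higher and 21 lower, and 9 stayed past the threshold whichever array was left out: tps6, bx1, GST25, m21, an2, gst5, GA20, zag2 and m1. The sign of all 61 held in those 6 fits, and 24 passed in none of them. In the planned fit over all probe sets, no call held whichever array was left out. There tps6 passed in 5 of the 6 fits, m21, an2 and bx6 in 1 each, and bx1 and GA20 in 0.

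**Figure D3:**
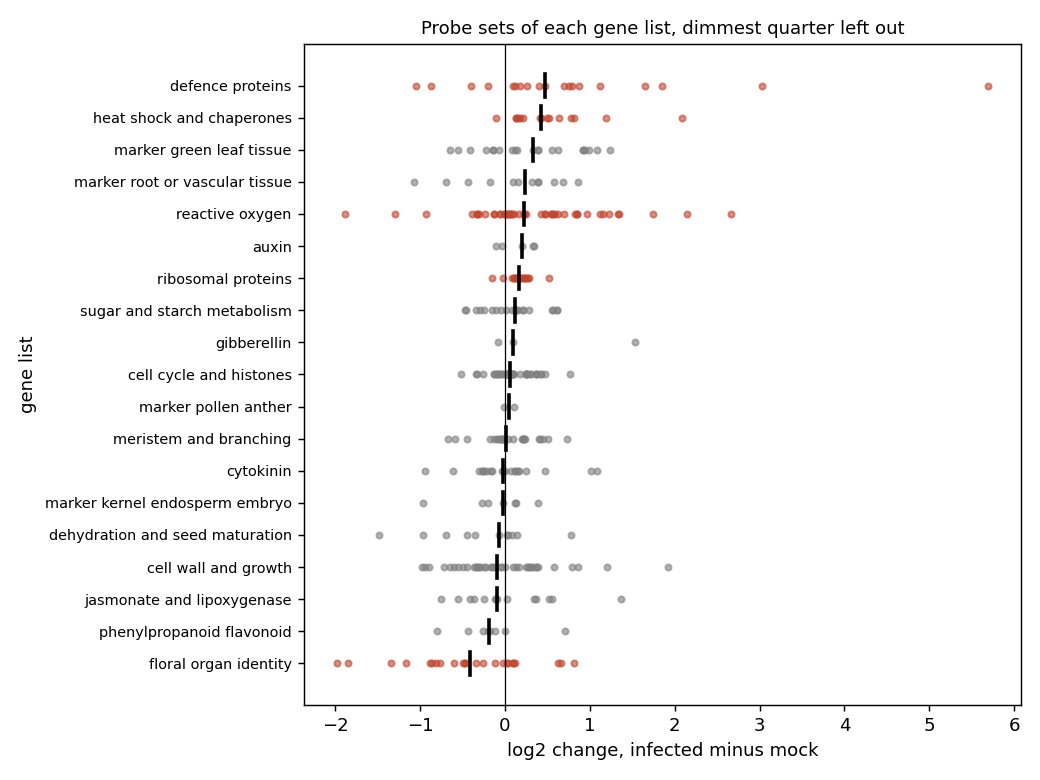
Log2 change (infected minus mock) of each probe set of the 19 gene lists, without the dimmest 25%. Red lists had a camera adjusted p under 0.05 over all probe sets at the preset correlation (none with an estimated correlation), black bars are medians, and tps6 lies farthest to the right at 5.69.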

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

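All tests in this part were chosen after the results they concern had been seen.

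Among 47 control probe sets at or above the floor on the infected arrays, which the comparisons leave out, 4 had every infected value above every mock value, where chance gives 5% in 1 direction. Over all probe sets off the floor, groups did not overlap in 23.5% (either direction, chance 10%), so the control probe sets do not stand out from the rest. They were gapdh (middle probe set) at 452 ± 82.2 (SD, n = 3) in infected and 256 ± 12.7 (SD, n = 3) in mock ears, 1.76-fold, a further gapdh middle probe set that reads several transcripts at 1610 ± 217 and 1080 ± 82.1, 1.49-fold, and ef1a probe sets at 1.10-fold (3' end) and 1.19-fold (middle).

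Of 24 probe sets of the floral organ list outside the dimmest 25%, 7 were lower in infected ears (6 with the replicate block), 1 was higher and 16 did not pass. A uniformly smaller share of floral tissue would lower all by a common factor only if they were read in that tissue alone and without background. Whether this holds was not tested. The 14 floral organ probe sets with a mock signal of at least 100 ranged from -2.41 ± 0.22 (m1) to 0.10 ± 0.15 (si1, SE). That is more than their errors allow (F test over n = 14 probe sets with limma's moderated errors from 3 arrays a group, p = 0.00023, and p = 0.000439 without m1). The F test treats probe sets read on the same arrays as independent. It speaks against 1 common factor but does not decide on a smaller share of floral tissue. The probe sets were assigned after their values had been seen, and this F test replaced a chi-square test that treats the errors as known, after the result of that test had been seen. With the 3' to 5' control ratio of each array as a covariate, the median change of the 7 lower list members was -1.16 before and after (median SE 0.16 both times), while 4 of the 7 kept a call among the 157 made with it. The covariate moved changes over all probe sets by a median of 0.0355, less than their median SE of 0.133, so RNA integrity stays open. A smaller share of floral tissue, unequal loss of some floral parts and a change in gene activity stay open as well.

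Of the green leaf list, lhcb5 and OEE3 rose in infected ears and the other genes did not pass, except 2 probe sets of lhcb6 with the replicate block. Mature leaf blade tissue among the infected ears would raise the abundant transcripts of carbon fixation as well as those of the light reactions. The C4 genes pdk1, me3 and mdh6 had a mean change of -0.07 (SD 0.21) against 0.81 (SD 0.33) for 7 light-harvesting and photosystem genes. Exact permutation of the classes over genes gave p = 0.00833, the smallest these genes allow, and 0.0101 with rbcs1 and rca1 on the first side. It treats genes read on the same arrays as independent. With fdx2 and fnr1 on the second side as well, 5 carbon fixation genes (0.15, SD 0.33) and 9 light reaction genes (0.56, SD 0.61) gave exact permutation p = 0.192. The C4 gene pep1, at the floor on all arrays and so without a measured rise, was left out of these comparisons. The result rests on which genes are compared, so leaf tissue in the infected samples stays open.

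The number of calls over all probe sets was low. Leaving out only the 4192 probe sets at the floor on all 6 arrays raised it from 52 to 286, and the prior degrees of freedom from 0.396 to 2.61, so these probe sets account for most of the difference between the fits. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many calls in either fit (52 and 355, highest other 1), and 10 splits are too few for a share under 0.05. The 3 other splits that part all 3 replicate pairs gave 0 calls and the 6 that part 1 pair at most 1.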

How the results depend on the processing

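Signal near the floor limits these results. Over all probe sets the count of 52 became 355 without the dimmest 25%, 263 without the dimmest 50%, 7 with the replicate block, 90 with a variance trend and robust fit, 88 with array weights, 2 at adjusted p under 0.01 and 24 at 2-fold or more, and 48 to 64 under quantile normalization, floors of 1 and 64, without probe sets reading several transcripts, and averaging by gene. Leaving out 1 array gave 0 to 30. Among alternatives added after seeing the data, it was 286 without probe sets at the floor on all arrays, 310 without those at the floor on any array, 1 with arrays not scaled and, without the dimmest 50% by linear mean, 266 (337 with a trend, 339 with trend and robust fit, 660 with the block, 381 with array weights). Without the dimmest 25% the count of 355 became 591 with the block, 535 with array weights, 43 at adjusted p under 0.01 and 46 to 167 without 1 array, all added. Of the named results over all probe sets, 7 lost their call with the block and 1 gained a call. With a floor of 1, 3 lost and 7 gained a call. With a floor of 64, 1 lost and 1 gained a call, and with quantile normalization 1 lost and 2 gained a call. The 2% trimmed mean lost 1 call. For lists, 5 passed by camera with the preset correlation and 0 with an estimated one (each adjusted p 0.379). By fry 6 passed, and by fry mixed, which counts changes in either direction, 12 did. Both fry tests ask whether a list changed at all, not whether it changed more than other genes.

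Lists that did not pass changed direction in some settings, without a call. Cytokinin gave adjusted p 0.971 without the dimmest 25%, 0.245 without the dimmest 50%, 0.871 with the block, 0.816 with block and filter, 0.984 without probe sets reading several transcripts and 0.67 with 1 probe set per gene. Kernel gave 0.906 as first matched and pollen 0.801 with quantile normalization. Without 1 array, adjusted p ranged from 0.258 to 0.971 (meristem), 0.289 to 0.999 (auxin), 0.378 to 0.968 (cytokinin), 0.515 to 0.958 (jasmonate), 0.766 to 0.958 (pollen) and 0.427 to 0.958 (root). Log2 changes near 0 changed sign for prf5 (0.008 with array weights) and, without 1 array, an1 (-0.069 to 0.251), prf5 (-0.081 to 0.07), fea2 (-0.111 to 0.113), zfl1 (-0.155 to 0.095), ids1 (-0.149 to 0.014) and ts2 (-0.239 to 0.069). Where no value above shows a cause, the cause was not tested.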

Other observations

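The lists and classes in this part were chosen after the data were seen. Their list tests had no result when the expected outcome of those on folding, aquaporin and chromatin genes was written, but single members (pdi8, tip1, nip3a and pip1e) had been seen. The tests on MADS-box classes and glutathione transferases were chosen after their values had been seen.

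Of the MADS-box genes, 14 assigned to floral organ classes had a mean log2 change of -0.86 (SD 0.79) and 9 others of 0.33 (SD 0.39). Exact permutation of the classes over genes, which treats genes read on the same arrays as independent, gave p = 0.000439. M7, M8, m25 and zmm17, all with changes below 0, were in neither class. Counted among the others, they brought that mean to -0.02 (SD 0.67) and the exact permutation p to 0.00699. The 9 others included zmm19 (0.82) and m5 (0.67), both on the floral organ list. The 14 genes of floral organ classes included m1 (-2.41), which is outside that list. As the classes were assigned after the values were seen, these p-values do not decide whether the classes differ.

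Glutathione transferases were tested as a separate list of 35 probe sets because members had been seen to rise (camera p = 5.94e-07, adjusted p = 1.92e-06, and adjusted p = 0.127 with an estimated correlation). Without the dimmest 25% of probe sets, 8 of 30 rose, none fell and 22 did not pass, and with the replicate block 9 rose and 1, gst19, fell (adjusted p = 0.02). The genes that rose are those already counted in the reactive oxygen list, so this list adds no separate evidence. At the same adjusted threshold 355 of all 13215 probe sets passed, and 2309 of them lay under 0.05 by limma's unadjusted p.

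Small heat shock genes, 6 probe sets also chosen after members had been seen to rise, had adjusted p = 1.92e-06 by camera, and adjusted p = 0.127 with an estimated correlation. Outside the dimmest 25%, 3 rose (2 with the replicate block) and 3 did not pass.

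Protein folding genes of the endoplasmic reticulum had p = 0.0344 by camera, but adjusted p = 0.0573 over the 5 added lists and 0.571 with an estimated correlation. The single member that rose was pdi8 (0.88 ± 0.15, adjusted p = 0.0336). Aquaporin genes (camera over n = 38 probe sets, p = 0.0625, adjusted p = 0.0781) and chromatin genes (n = 78 probe sets, p = 0.0783) missed the threshold as lists. A p above 0.05 leaves a small common shift open, so the bound written before these tests was too lax to decide. The aquaporin gene nip3a changed by -0.57 ± 0.10 (adjusted p = 0.0336).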
